A study of Mus musculus with 18 samples.

How the data were processed

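Total RNA was isolated with an RNeasy Mini kit, labelled with biotin and hybridised to whole-transcript Affymetrix mouse gene arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA settings, versions, scan dates and genome build are not given in the sources used here, so array handling could not be tested as a batch. Strain is given as Black6-129X1/SvJ.

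The table held 41345 probe sets on 18 arrays, of which 190 were controls, 23521 had 1 gene symbol, 1814 several and 15820 none. Symbols came from the platform annotation, updated by gene ID through the RefSeq table of GRCm38.p6; 193 probe sets kept their old symbol. Each of 22180 genes took its probe set with the highest mean over the 18 arrays; 1082 genes had more than 1. No coordinates are given, since the build behind the probe sets is not named. Genes were tested where the value reached the median of its array on at least 3 of the 12 time-course arrays, which left 13865.

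Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg, adjusted p threshold 0.05). The AGi effect was fitted with the day as a block, since each day holds 1 array of each arm (5 residual degrees of freedom). Slopes over day came from a model of arm, day as a number and their product (8 residual degrees of freedom). This model did not pair the arms by day, so changes of a day shared by both arms count in its spread. As no arm and day was repeated, and nothing says that days were separate cultures, p-values measure the spread between days, of whatever source. Of 29 gene lists, 25 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Positions were compared with an exact two-sided sign-flip permutation test over days. Single arrays were compared by size only, and a list's median by its percentile among 10000 random lists matched on 20 bins of mean expression. The random lists were not matched on how far genes move together, so such a percentile is no p-value.

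Lists, designs and alternatives were chosen before the data were examined, unless said otherwise. Named genes were chosen by a rule set at the same time: the 12 highest and 12 lowest AGi effects past the threshold with 1 sign on all 6 days, the 6 highest and lowest slopes, the 8 highest and lowest single-array differences, up to 4 members per list (3 for single arrays), and 9 key genes. Alternatives were other filters, probe set rules, normalization, variance models, day terms and thresholds, and leaving out each day.

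The fits were tested on simulated arrays with the real means and residual spread and 200 changed genes among 13865. For the AGi effect, 56.7% of genes changed by 0.5 log2 were recovered, 89.6% at 1 and 97.0% at 2, with 9 unchanged genes called. For the slope difference, 25.4% were recovered at 0.1 log2 per day, 82.1% at 0.2 and 100% at 0.4, with 6 unchanged genes called. The simulation held no technical difference between the arms. The hybridisation controls were examined after the results were seen, when control probe sets were found among the called ones, and 2 alternatives based on them were then added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.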

Results

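Gene expression was measured on 18 microarrays of mouse cells. Reprogrammable mouse embryonic fibroblasts (MEFs), which carry inducible OKSM (Oct4, Klf4, Sox2 and Myc), were cultured with OKSM alone or with OKSM plus AGi, the combination of ascorbic acid and a GSK3 inhibitor. Each arm was sampled on days 2, 4, 6, 8, 10 and 12, with 1 array per arm and day. The other arrays were single samples of MEFs without dox, granulocyte-macrophage progenitors (GMPs), embryonic stem cells (ESCs), iPSCs made from fibroblasts with 96 hours of AGi induction (Fibroblast-iPSC), iPSCs made from GMPs with 48 hours of it (GMP-iPSC) and Thy1-positive cells sorted from OKSM cultures on day 3. No condition was repeated, so the spread behind every error and p-value of the time course is that of the 6 days, and the number of arrays limits the precision. Array medians lay between 6.32 and 6.46 on the log2 scale.

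The first comparison asked how AGi changed the cultures across the 6 days. Of the genes tested, 19 of 37 of the pluripotency network and 25 of 35 of epithelial cells were higher with AGi, and 36 of 43 of fibroblasts and 25 of 31 TGF-beta targets were lower. The calls on these lists were lost with an estimated correlation (adjusted p = 0.690 with an estimated correlation for the pluripotency list, adjusted p = 0.583 with an estimated correlation for the others). Nanog, a core pluripotency factor, was higher by 2.17 ± 0.48 (log2, limma SE, n = 6 days, adjusted p = 0.0106) and Tfcp2l1, a naive pluripotency factor, by 2.40 ± 0.36 (adjusted p = 0.0025), both on 6 of 6 days. Cdh1, the epithelial cadherin, was higher by 2.10 ± 0.40 on 5 of 6 days (adjusted p = 0.0061). Thy1, a fibroblast surface marker, was lower on all 6 days (−0.91 ± 0.19, adjusted p = 0.0079). Hey2, a Notch target, had a difference of −2.66 ± 0.07, also on all 6 days.

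With the day as a block, limma called 2722 genes higher and 2675 lower with AGi, 38.9% of 13865 tested. Of these, 162 were higher and 373 lower by at least 1 log2. Part of this count lay within a measured difference between the arrays of the arms: all 18 probe sets of the hybridisation controls, which are added after labelling and come from no cell, read higher with AGi, by 0.06 to 0.26. Their mean difference was 0.17 ± 0.07 (SD over 6 days, exact sign-flip permutation p = 0.03125). With limma, 11 of these 18 control probe sets were themselves called, so a call alone does not show a difference of the cells. Of the 5397 called genes, 790 differed by no more than the largest control. Tested against that control difference instead of 0, 429 genes were higher and 754 lower. All 24 of the genes named for size below passed that test too; of the other genes named in this comparison, Sox2 (adjusted p = 0.104), Thy1 (adjusted p = 0.0524), Csf1r (adjusted p = 0.0760) and Nkd1 (adjusted p = 0.238) did not.

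The highest differences belonged to Bex1 (2.76 ± 0.21), Ccdc141 (2.68 ± 0.35), Cnpy1 (2.63 ± 0.41), Adh7 (2.49 ± 0.34), Nefl (2.48 ± 0.40), Mpzl2 (2.42 ± 0.44), Tfcp2l1, Nanog, Zfp296 (2.15 ± 0.18), Ap1m2 (2.10 ± 0.48), Aim2 (2.05 ± 0.36) and St14 (2.00 ± 0.24). The lowest belonged to Tac2 (−3.33 ± 0.69), Fabp7 (−2.97 ± 0.22), Gabra2 (−2.88 ± 0.42), Pde2a (−2.68 ± 0.22), Hey2, Rtl3 (−2.57 ± 0.22), the imprinted growth factor gene Igf2 (−2.56 ± 0.32), Tnfrsf11b (−2.48 ± 0.25), Nxpe2 (−2.47 ± 0.51), Islr (−2.45 ± 0.47), Ppbp (−2.43 ± 0.39) and Ptprz1 (−2.35 ± 0.32). Among the reprogramming factors, Sox2 differed by 2.07 ± 0.63 (adjusted p = 0.0325, 5 of 6 days) and Myc by −1.09 ± 0.08 (adjusted p = 0.0006). Klf4 (−0.02 ± 0.07, adjusted p = 0.836) and Pou5f1 (0.15 ± 0.12, adjusted p = 0.322) did not pass. Whether the probe sets of these factors read the induced OKSM, the cells' own genes or both is unknown. The Pou5f1 probe set read 8.13 in ESCs against 6.80 in MEFs, so how well it follows Pou5f1 is unknown, and its result does not settle whether Pou5f1 differed. Axin2, a target of beta-catenin, was higher by 0.92 ± 0.14, and the Meg3 probe set differed by 0.11 ± 0.10 (adjusted p = 0.409). The Meg3 probe set read 7.07 in MEFs and 6.59 in GMPs, while Rian, of the same cluster, read 10.58 and 5.61, so whether it measures Meg3 is unknown. With day left out of the model, Nanog (adjusted p = 0.119), Sox2 (adjusted p = 0.163) and Thy1 (adjusted p = 0.0841) no longer passed.

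The calls on lists given here were made with camera at a preset correlation and were lost with an estimated one (for the collagen and macrophage lists, adjusted p = 0.583 with an estimated correlation). Of 43 fibroblast genes, 36 were lower with AGi and 1 was higher (adjusted over the list alone, also 36 and 1). Examples are S100a4 (−1.72 ± 0.17), Snai2 (−1.20 ± 0.11), Col6a3 (−1.10 ± 0.09) and Fbln2 (−1.07 ± 0.09). Of 31 TGF-beta targets, 25 were lower (29 adjusted over the list alone), among them Myl9 (−1.71 ± 0.18) and Ccn2 (−1.71 ± 0.19). Of 22 collagen-modifying genes, 14 were lower and 1 higher, with Crtap at −0.62 ± 0.08 and Loxl1 at −0.93 ± 0.14. Of 35 epithelial genes, 25 were higher and 1 lower (28 and 1 adjusted over the list alone), with Grhl3 at 1.87 ± 0.22, Dsc2 at 1.07 ± 0.13 and Ehf lower at −1.72 ± 0.24. Of 37 pluripotency genes, 19 were higher and none lower (21 adjusted over the list alone), with Gdf3 at 1.56 ± 0.28; 11 were higher without day 8 and 11 without day 10. Macrophage markers moved with the arm as well: 13 of 19 were lower and 1 higher (17 and 1 adjusted over the list alone), with Csf1r at −0.63 ± 0.12. The list median did not fall steadily: it was −0.33 on day 2, −0.11 on day 4 and −0.15 on day 6. It was −1.01 on day 8 and −1.43 on day 12. From day 6 to day 8 the mean over its 29 measured genes rose from 6.36 to 7.24 in OKSM cultures, and rose less with AGi. Without day 8, 6 macrophage markers were lower, without day 10 5 and without day 12 7.

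With a preset correlation, camera called these 6 lists and those of the cell cycle (12 of 38 higher, 1 lower), myeloid progenitors (9 of 22 lower, 1 higher) and primitive endoderm (8 of 23 lower, 1 higher). The cell cycle count was 25 higher without day 2, 6 without day 6, 2 without day 8, 4 without day 10 and 7 without day 12, and 4 myeloid progenitor genes were lower without day 8, 4 without day 10 and 5 without day 12. The primitive endoderm call was lost without day 4 (adjusted p = 0.0752) or day 6 (adjusted p = 0.0918). None of the 9 calls held with an estimated correlation: the smallest adjusted p = 0.583 with an estimated correlation. With fry, which does not set a list against other genes, the pluripotency (adjusted p = 0.0765) and cell cycle (adjusted p = 0.136) lists did not pass. The fibroblast and TGF-beta (adjusted p = 0.0045 each), collagen, myeloid progenitor, primitive endoderm, epithelial and macrophage (adjusted p = 0.0408) lists passed with fry. It also called lists that camera did not, such as the endothelial one. Of 24 beta-catenin targets, 8 were higher, such as Lef1 (1.17 ± 0.25) and Nkd1 (0.38 ± 0.06), and 5 lower, such as Trabd2b (−1.84 ± 0.22), and the list was not called (adjusted p = 0.698). The median, the mean and the camera direction differed in sign for the beta-catenin, keratinocyte, mesendoderm, p53 and TET and Jumonji lists. On days 2, 4 and 6 alone, 799 genes were higher and 1034 lower, and without day 8, 1692 were higher. On those 3 days the lists of pluripotency (3 higher, 1 lower, adjusted p = 0.130), the cell cycle (0 higher, 1 lower, adjusted p = 0.50) and myeloid progenitors (1 higher, 1 lower, adjusted p = 0.130) were not called with camera. The epithelial list (6 higher, 2 lower) and those of fibroblasts (20 lower), TGF-beta targets (19), collagen modification (6), macrophages (3), primitive endoderm (2) and, on these days only, endothelial cells (2, adjusted p = 0.0389) were. All of these calls were lost with an estimated correlation (smallest adjusted p = 0.685 with an estimated correlation). On days 8, 10 and 12 alone, primitive endoderm was not called (adjusted p = 0.317), and imprinted genes were called lower (9 lower, 3 higher, adjusted p = 0.0347, but adjusted p = 0.413 with an estimated correlation).

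**Figure D1:**
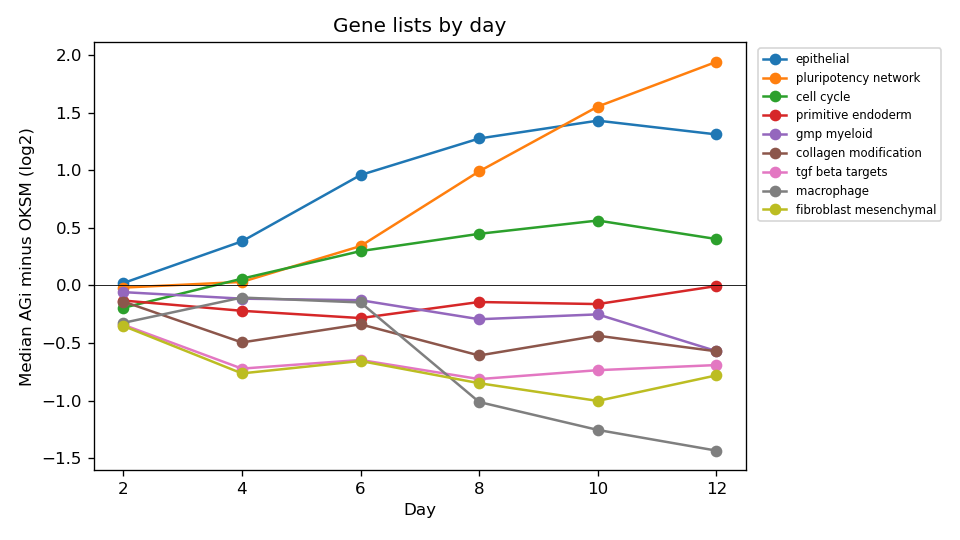
Median difference of AGi minus OKSM (log2, vertical axis) over the tested genes of each called list, by day (horizontal axis). The median of the pluripotency network was −0.02 on day 2 and 1.94 on day 12, while the fibroblast list was below 0 on every day.

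**Figure D2:**
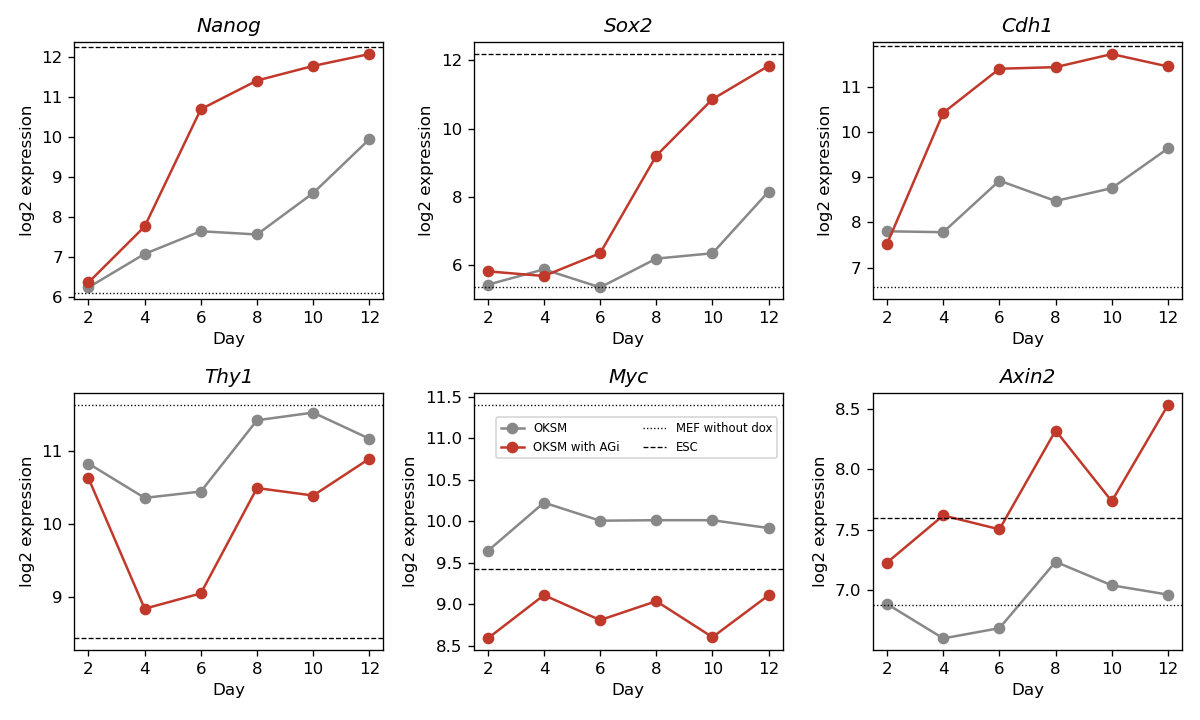
Log2 expression (vertical axis) of 6 genes by day (horizontal axis) in OKSM cultures and in OKSM cultures with AGi, 1 array per point, with horizontal lines at the MEF (dotted) and ESC (dashed) levels. Nanog reached 12.08 with AGi on day 12, against 9.95 without.

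The next comparison asked whether the arms drew apart with time. Of 37 pluripotency genes, 14 had a higher slope over days with AGi, and genes led by Tac2 had a lower slope with it. Tdgf1, a Nodal co-receptor, gained 0.52 ± 0.12 more log2 per day with AGi (adjusted p = 0.0428), and Zfp42, a marker of naive pluripotency, 0.42 ± 0.07 more (adjusted p = 0.0095). Cyp2b23 (0.51 ± 0.08), Mir290a (0.44 ± 0.07), Triml2 (0.43 ± 0.09) and Lrrc31 (0.42 ± 0.06) had the other high slope differences. The lowest belonged to Tac2 (−0.51 ± 0.10), Cxcl15 (−0.50 ± 0.11), Lgr5 (−0.45 ± 0.10), Wfdc17 (−0.44 ± 0.10), Sparcl1 (−0.42 ± 0.07) and Nxpe2 (−0.41 ± 0.08).

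In all, the slope was higher with AGi for 244 genes and lower for 180 (limma, 8 residual degrees of freedom). Adjusted over the list alone, 29 pluripotency genes had a higher slope, and the list was called with the preset correlation and with the estimated one (adjusted p = 0.0338 with an estimated correlation). The latter call was lost without day 2 (adjusted p = 0.308), day 4 (adjusted p = 0.101), day 6 (adjusted p = 0.0930) or day 8 (adjusted p = 0.0889), and 4 of the genes had a higher slope without day 4, 3 without day 10 and 7 without day 12. Of 35 epithelial genes, 13 had a higher slope (19 adjusted over the list alone; 8 without day 2, 7 without day 4 and 8 without day 10), with adjusted p = 0.0652 with an estimated correlation, and without day 12 adjusted p = 0.0239 with an estimated correlation. With the preset correlation, camera also called the slopes of the cell cycle (7 of 38 higher, 21 over the list alone), germline (1 of 7), hypoxia (1 of 30) and TET and Jumonji (1 of 25, 1 lower) lists higher, and those of the macrophage (0 of 19, median −0.15), fibroblast (0 of 43) and interferon (1 of 19) lists lower. None of these 7 held with an estimated correlation (smallest adjusted p = 0.448 with an estimated correlation). Of them, only the cell cycle and macrophage calls held without each day, with 1 cell cycle gene higher without day 2, 1 without day 4, 3 without day 6, 3 without day 8 and 2 without day 10, and 6 macrophage markers lower without day 2. The counts depended on single days and on the shape of the trend: without day 4 they were 51 and 43, without day 8 108 were lower, without day 10 94 and 58, and without day 12 113 and 40. With the day as a block, the late minus the early days gave 89 higher and 250 lower, and 114 of the 424 genes were still called. With a separate level for days 8 to 12 in each arm, a term added after the data were seen, limma called 0 genes. At an unadjusted p under 0.05 there were 676 of 13865 genes, about as many as chance gives.

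Within OKSM cultures, the change with day asked which genes rose or fell without AGi. Penk, which encodes an opioid precursor, gained 0.69 ± 0.14 log2 per day (adjusted p = 0.0151), Mmp3, a matrix metalloproteinase, 0.53 ± 0.08, and Lum, a matrix proteoglycan, 0.47 ± 0.09. Tac2 (0.60 ± 0.07), Cxcl15 (0.59 ± 0.08) and Lgr5 (0.47 ± 0.07) rose too. Kcnma1, a potassium channel gene, fell by 0.70 per day (SE 0.16, adjusted p = 0.0249), and Mir669h, Mir466b-2, Olfr310, C1qtnf3 and Mir297a-4 followed. From day 6 to day 8 alone, Penk rose by 5.08, Lum by 3.31 and Mmp3 by 3.06 log2. With a separate level for days 8 to 12, no slope in OKSM cultures passed, rising or falling (limma, smallest adjusted p = 0.305). The slopes of Kcnma1 (0.0353), Olfr310 (0.0416) and Mir297a-4 (0.0136) were then above 0. In total 709 genes rose and 537 fell, against 606 and 736 when the arrays were quantile normalized again. Without day 4 these were 221 and 120, without day 10 204 and 138, without day 12 366 and 281, and without day 8 289 fell.

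With AGi, the 6 highest slopes were those of Tdgf1 (0.75 ± 0.08 log2 per day), Utf1 (0.70 ± 0.08), Sox2 (0.69 ± 0.08), Mmp13 (0.69 ± 0.09), Cyp2b23 (0.65 ± 0.06) and Nanog (0.59 ± 0.08); gene lists were not tested on the slopes within an arm. Kcnma1 (−0.69 ± 0.16), Necab1 (−0.40 ± 0.06), Mir297a-4, Mir669h, Olfr310 and Epha3 (−0.32 ± 0.05) fell. With a separate level for days 8 to 12, the slopes of Mir669h (0.10) and Olfr310 (0.0024) were above 0. In total 1461 genes rose and 1141 fell, against 878 and 622 without day 4 and 577 and 305 without day 12. When the arrays were quantile normalized again, 1282 rose and 1326 fell. From day 6 to day 8, 472 genes differed by at least 1 log2 in OKSM cultures, against 27 from day 4 to 6 and 17 from day 8 to 10; with AGi these counts were 253, 89 and 60, below the 444 from day 2 to 4 and the 361 from day 10 to 12. With a separate level for days 8 to 12, limma called 0 genes with a slope in OKSM cultures, and 48 rising and 34 falling with AGi. In OKSM cultures 731 of 13865 genes had an unadjusted p under 0.05, about as many as chance gives.

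**Figure D3:**
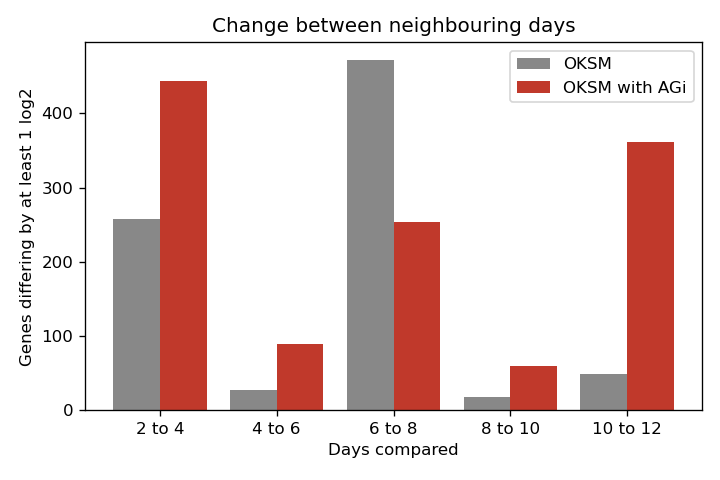
Number of genes (vertical axis) that differed by at least 1 log2 between neighbouring sampling days (horizontal axis), in OKSM cultures and in OKSM cultures with AGi. The interval from day 6 to day 8 held 472 genes without AGi, the most of its 5 intervals, and 253 with AGi, which had 444 from day 2 to 4 and 361 from day 10 to 12.

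The position of each culture between MEFs (0%) and the mean of the 3 pluripotent arrays (100%) was taken over 185 genes at least 3 log2 higher in the pluripotent arrays and 157 at least 3 log2 higher in MEFs. For the pluripotent-high genes, cultures with AGi stood at 4.81% on day 2, 25.8% on day 6 and 84.8% on day 12, and OKSM cultures at 5.26%, 7.19% and 24.3%. The mean difference was 28.2 ± 25.2 points (SD, n = 6 days, higher on 5 of 6 days), which did not pass (exact two-sided sign-flip permutation p = 0.0625; the smallest p for 6 pairs is 0.03125). Measured instead as the percent of these genes past 50% of the way, an alternative added later, the difference was 26.8 ± 24.2 points on 6 of 6 days (n = 6, exact permutation p = 0.03125). For the MEF-high genes, where a higher position means a lower level, the difference was 27.8 ± 8.46 points on 6 of 6 days (n = 6, exact permutation p = 0.03125). OKSM cultures stood at 44.6% on day 6 and 19.6% on day 8 for these genes, and cultures with AGi at 69.5% and 51.9%.

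**Figure D4:**
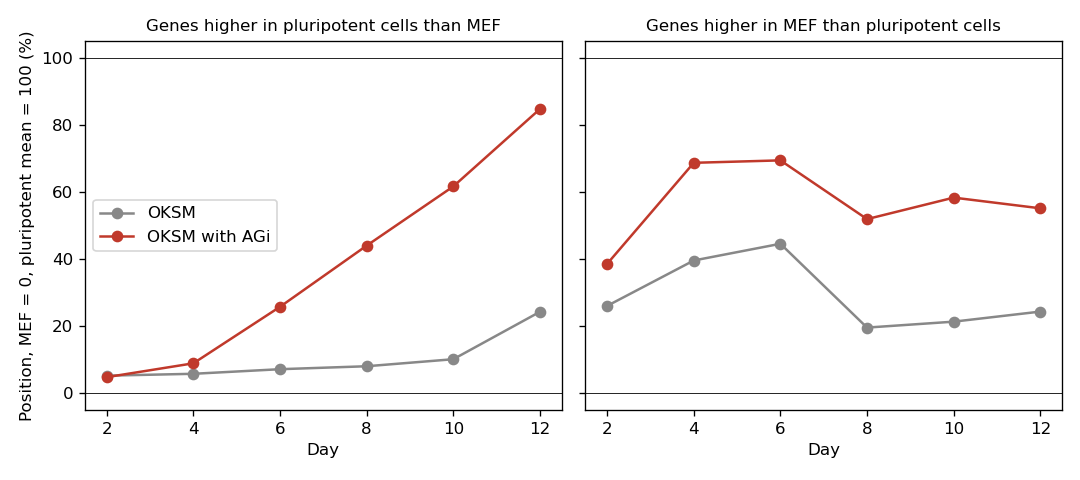
Position (vertical axis, percent of the way from MEFs to the pluripotent mean, median over genes) by day (horizontal axis), 1 array per point. For genes high in pluripotent cells the AGi culture reached 84.8% on day 12 and the OKSM culture 24.3%.

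The iPSC lines were compared with ESCs, 1 array each, so that no difference has a replicate check. Nanog and Sox2 lay within 0.06 of the ESC level in Fibroblast-iPSC and in GMP-iPSC. Fibroblast-iPSC had 347 genes higher and 226 lower than ESCs by at least 1 log2. The highest were Gm364 (5.59), Gm11543 (4.65), Tdpoz3 (3.99), Gm11546 (3.90), Zscan4e (3.54), the imprinted gene Mest (3.53), Usp26 (3.47) and Zscan4b (3.44). The lowest were Oasl2 (−2.84), Phlda2 (−2.54), Gna14 (−2.41), Apela (−2.32), Mir363 (−2.21), Pou2f3 (−2.19), Map7d3 (−2.13) and Pstpip2 (−2.13). Genes of the 2-cell-like state had a median of 1.19 over 18 genes and fibroblast genes of 0.98 over 39, both above all 10000 random lists matched on expression, and epithelial genes of −0.41. Such a place was not rare here. The collagen, inflammatory and TGF-beta lists also lay above all random lists. The epithelial, hypoxia and primed epiblast lists lay below all of them.

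GMP-iPSC had 129 genes higher and 158 lower than ESCs. Gm364 (5.33), Mest (4.32), Nxf3 (3.46), Slc13a5 (3.17), Usp26 (3.13), AV320801 (3.00), Efhc2 (2.89) and Fthl17b (2.89) were highest. Among the lowest were genes of the imprinted Dlk1-Dio3 cluster, which holds many small RNAs: AF357355 (−4.12), Mir453 (−3.72), AF357425 (−3.58), Rian (−3.34), AF357426 (−3.14) and Mir377 (−3.01). The immediate early genes Fos (−3.06) and Fosb (−3.04) were also among the 8 lowest. Fibroblast genes had a median of −0.58, below all random lists, as were the hypoxia and interferon lists. Genes of the 2-cell-like state had a median of 0.40 over 16 genes and p53 genes of 0.53 over 27. Both lay above all random lists, so higher 2-cell-like genes were not particular to Fibroblast-iPSC. Both iPSC lines were set against the same ESC array, so genes that differ in both are not independent.

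A trace of the donor cell was sought by comparing the iPSC lines directly, which differ in the hours of AGi induction (96 and 48) as well as in the donor, so that these cannot be told apart. The 140 genes marking MEFs had a median of 1.11 higher in Fibroblast-iPSC than in GMP-iPSC, above all 10000 random lists, and 131 of them were higher, led by Cdh11 (3.52), Tgfb3 (3.05) and Ccdc80 (3.00). For the 218 genes marking GMPs, the median was 0.07, also higher in Fibroblast-iPSC than in GMP-iPSC, at percentile 99.75 of random lists, with 141 of them higher. All 25 fibroblast-list genes at least 3 log2 higher in MEFs than in GMP-iPSC were higher in Fibroblast-iPSC. Choosing them partly by a low GMP-iPSC level favours this direction, so the count is no separate evidence of a donor trace.

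Thy1-positive cells of day 3 were compared with the mean of the OKSM cultures of days 2 and 4. Thy1 itself was 0.64 higher. By at least 1 log2 and outside both cultures, 74 genes were higher, led by Penk (2.68), Nrn1 (2.45), Apln (2.30), Gjb2 (2.23), Pparg (2.16), Cxcl5 (2.06), Lrrc32 (2.01) and Tslp (1.96). The 90 lower genes were led by Kcnma1 (−5.33), Gabra2 (−2.42), C1qtnf3 (−2.33), Scarna6 (−2.29), Snora44 (−2.24), Unc5d (−1.93), Mcam (−1.89) and Fabp7 (−1.89). Several named genes also changed by at least 1 log2 in both arms from day 6 to day 8. From the level before that step to the level after it, Thy1-positive cells stood at 98.6% for Kcnma1, 106% for C1qtnf3 and 49.6% for Penk. Scarna6, Snora44, Unc5d, Nrn1 and Lrrc32 stood at 91.0% to 529%. The other named genes were not among those of that step. A fibroblast preparation shared with the later days stays open, so the differences of the step genes may not come from the sorting. Fibroblast genes had a median of 0.24 over 40 genes, above all random lists, and pluripotency genes of −0.22 over 28. Macrophage markers had a median of −0.23. Lists were not required to lie outside both cultures. The mean over the measured fibroblast genes was 10.15, against 10.14 in OKSM cultures on day 2 and 9.67 on day 4, so it equalled day 2. For macrophage markers it was 6.61, between 7.36 on day 2 and 6.27 on day 4. The pluripotency mean, 7.06, lay below both (7.13 and 7.38).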

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

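The tests on the large AGi differences (day 10, then the slope on the controls, then their size), the gradual change, small RNA in the step, the shared preparation and the fibroblast RNA in ESCs were chosen after their results had been seen.

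Of 62 groups of 6 arrays, 7 held a day far from the others, where chance gives about 1 in 20. For the pluripotent-high genes the OKSM culture of day 12 stood at 24.3%, with the next at 10.2%, and its mean over the pluripotency list was 8.18, with the next at 7.51. With AGi, germline genes silenced by DNA methylation had a mean of 7.0 on day 12, with the next at 5.70, and 2-cell-like genes 6.21. The macrophage list stood at 7.17 with AGi on day 2, with the next at 6.5, and the trophoblast list at 6.23. In OKSM cultures the macrophage list stood at 7.36 on day 2 and at 6.27 on day 4. Keratinocyte genes stood at 6.23 in OKSM cultures on day 10. The pluripotency list differed between the arms in its slope, with a median of 0.23 log2 per day, a call lost with an estimated correlation without day 2, 4, 6 or 8.

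The AGi effect stood beside a difference of the arrays themselves: 18 of 18 hybridisation control probe sets read higher with AGi. Chance is argued against for the arms within days, if the days can be exchanged. Of 32 assignments of the arms, 1 gave 5397 genes or more, the real one, and the highest of the others gave 0. A share of 1 of 32 is the smallest that these assignments allow. If each arm was 1 culture sampled on all days, they do not test a chance difference between the cultures. Exchanging the arms on 1 day gave a smallest adjusted p of 0.0796 with limma, so the 0 is no wide margin. A difference of the size the controls show is argued against for genes differing by at least 1 log2: on days not used to choose them, their median exceeded the largest control of the day by 0.87 on average (95% bounds 0.35 and 1.39, lowest bound without 1 day 0.16), though on day 2 by 0.03 only. The bounds treat the days as independent, although overlapping sets of days chose these genes, so they may be too narrow. Any other technical difference that follows the arm, such as handling before hybridisation, stays open: on day 10, a single pair of arrays where the controls fell to 20.9% of the other days, the median was 127% for these genes and 101% (quartiles 53.6% and 160%) for 323 genes within the range of the controls, which cannot be told apart from a technical difference, and the slope on the controls over all days had wide 95% bounds (−1.30 to 0.52 for the larger differences).

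Both arms stepped between day 6 and day 8, with 161 genes changing by at least 1 log2 the same way, 129 up and 32 down, and 1 in opposite ways, although with AGi more genes changed from day 2 to 4 and from day 10 to 12. A gradual change is argued against across the arms: of 472 genes chosen in OKSM cultures, 68.2% had their largest change of the 5 intervals there with AGi, as did 83.0% of 253 chosen with AGi in OKSM cultures. A lower recovery of small RNA, which bears on the falling genes alone, stays open for these: 18 of 32 (56.2%) were small RNA genes, against 1.62% of all tested, and of 224 tested small RNA genes 67.4% fell without AGi and 71.4% with it. A fibroblast preparation shared by days 8 to 12 and the Thy1-positive cells also stays open: these cells stood 37.9% of the way at the median gene (quartiles 8.43% and 71.4%), but MEFs without dox stood at 30.8%, and the Thy1-positive cells were close to days 8 to 12 for Kcnma1 (98.6%) and Hoxd13 (89.4%) but not for Postn (−8.91%). A change of the cultures themselves was not tested, and days and any array batch cannot be told apart, as no batch is given.

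Day order itself passed for the slope difference (424 genes, 1 of 100 orders as large, highest other 0), the OKSM trend (1246, 1 of 100, highest other 651) and the AGi trend (2602, 1 of 100, highest other 2134), but these random orders held few close to the real one. Exchanging 2 neighbouring days gave 2 to 245 genes for the slope difference, 1 to 1175 for the OKSM trend and 1115 to 2644 for the AGi trend. The highest of each came from days 2 and 4, and for the AGi trend it was above the real 2602.

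The Dlk1-Dio3 cluster was low in GMP-iPSC: 21 of its 55 measured genes were lower than in ESCs by at least 1 log2, against 5 in Fibroblast-iPSC and at most 4 in any of 20920 other windows of as many neighbouring genes. Fibroblast RNA in the ESC sample is argued against as the source of its Rian level. Abundant fibroblast genes reached 11.8% of their MEF level there (upper quartile 15.9%) and Rian 76.8%. A smaller share of fibroblast RNA in the ESC sample is not excluded by this. A lower recovery of small RNA is argued against by 184 small RNA genes outside the cluster, with a median of −0.0065 against −1.44 for 26 inside. Silencing of the cluster in this line, or a state kept from GMPs, where Rian read 5.61, stay open and were not tested, as each is 1 array.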

How the results depend on the processing

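The tests with days 2, 4 and 6 or days 8, 10 and 12 alone, with a term for days 8 to 12, against the hybridisation controls and on the slopes of lists without 1 day, and those of the percent of genes past 50% of the way, were chosen after seeing the data.

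Of the main results under the alternatives, 127 kept their direction and side of the threshold or moved little, 52 moved, 8 lost and 5 gained the threshold. With the replicate block of day left out, AGi gave 2047 genes higher and 1829 lower. Requiring 1 log2 left 162 and 373, the test against the controls 429 and 754, and days 2 to 6 alone 799 and 1034 with 1 list higher. Leaving out each day in turn gave 1692 to 2884 higher. An estimated correlation called 0 and 0 lists, and fry 10 lower. For the slope difference, leaving out days gave 51 to 271 higher and 40 to 213 lower, log2 of day 124 and 62, and the late minus the early days 89 higher and 250 lower, against 244 and 180. In OKSM cultures leaving out days gave 204 to 1019 rising and 120 to 474 falling, and log2 of day 395 rising; with AGi 577 to 1941 and 305 to 1342, and 899 and 716. The term for days 8 to 12 left 0 and 0 for the slope difference, 0 and 0 in OKSM cultures and 48 and 34 with AGi in limma (676, 731 and 1912 at an unadjusted p under 0.05). With 13865 genes tested, 676 and 731 are about as many as chance gives. The pluripotent-high position passed with genes differing by at least 2 (26.6 points) or 4 (29.9), with ESCs alone (28.4), with the mean over genes (22.6) and as the percent of genes past 50% of the way (26.8). It was 7.10 points on days 2 to 6, 49.3 on days 8 to 12 and 21.8 to 33.9 without 1 day. The MEF-high position was 22.2, 33.4 and 25.9 to 30.8. With 3 or 5 days the exact test cannot reach the threshold (smallest p 0.25 and 0.0625), so these give sizes only. A difference of at least 2 log2 left 42 and 10 genes in Fibroblast-iPSC, 20 and 17 in GMP-iPSC and 7 and 5 in Thy1-positive cells. Against day 2 alone these cells had 115 higher, and against day 4 alone 125 higher and 156 lower. MEF-marking genes at 2 log2 gave 0.61 and at 4 log2 1.83. A larger required difference lowers counts by construction; for the rest the cause was not tested.

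The 51 reversals among named genes were of values with p above 0.05 under the alternative. With the mean over probe sets this was Axin2 (OKSM slope, −0.00480). Leaving out each day in turn gave Cdh1 −0.0583 to 0.34 (slope difference), Myc −0.0288 to 0.0287 (slope difference), Pramel12 −0.0164 to 0.0595 (slope difference), Rian −0.0275 to 0.00293 (slope difference), Tdpoz2 −0.00190 to 0.0528 (slope difference), Tfrc −0.00904 to 0.15 (slope difference), Thy1 −0.0642 to 0.14 (slope difference), Klf4 −0.0661 to 0.0115 (AGi effect), Klf4 −0.0433 to 0.0174 (AGi slope), Meg3 −0.0266 to 0.0204 (AGi slope), Myc −0.0104 to 0.0388 (AGi slope), Myc −0.0303 to 0.0283 (OKSM slope), Pou5f1 −0.0190 to 0.00516 (OKSM slope). With log2 of day it was Thy1 (slope difference, −0.0672). On days 2, 4 and 6 it was Begain (AGi effect, 0.10), Slc4a1 (AGi effect, −0.0543), Rhox5 (AGi effect, −0.0242), Pou5f1 (AGi effect, −0.10), Xist (AGi effect, 0.00396), and on days 8, 10 and 12 Epor (AGi effect, 0.0149), Klf4 (AGi effect, 0.0506). With the term for days 8 to 12 it was Rian (slope difference, 0.0274), Epor (slope difference, −0.000790), Slc4a1 (slope difference, −0.0457), Spi1 (slope difference, 0.00670), Vav1 (slope difference, 0.00817), Lefty2 (slope difference, −0.0426), Nes (slope difference, −0.0291), Plagl1 (slope difference, 0.0159), Klf4 (slope difference, −0.0182), Gm4340 (slope difference, −0.00601), Thy1 (slope difference, −0.0675), Kcnma1 (OKSM slope, 0.0353), Olfr310 (OKSM slope, 0.0416), Mir297a-4 (OKSM slope, 0.0136), Pou5f1 (OKSM slope, 0.0247), Klf4 (OKSM slope, 0.0381), Thy1 (OKSM slope, −0.0795), Axin2 (OKSM slope, −0.0590), Mir669h (AGi slope, 0.10), Olfr310 (AGi slope, 0.00244), Klf4 (AGi slope, 0.0199), Thy1 (AGi slope, −0.15). The cause was not tested. Of the other named values, 3989 kept their direction and side, 442 lost and 44 gained the threshold and 5 moved. No background level was used here, so the signal under which small differences are lost is unknown.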

Other observations

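The fibroblast RNA test was written before its result was seen, while Dazl, Gm364, the X-linked genes and the tests on days 2, 4 and 6 or 8, 10 and 12 alone were chosen after their values were seen.

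Germline genes stood higher in the day 12 culture with AGi than in the earlier ones. Dazl, a germ cell RNA-binding protein, read 9.99 on that array, 5.41 on day 10 and 4.59 in the OKSM culture of day 12. Gm364 read 9.76 with AGi on day 12, 10.6 in Fibroblast-iPSC and 5.03 in ESCs. Imprinted genes moved in both directions with AGi: 7 of 25 were lower and 2 higher, and on days 8, 10 and 12 alone the list was called lower (9 and 3, adjusted p = 0.0347, but adjusted p = 0.413 with an estimated correlation), with Mest over all days at −1.83 ± 0.22, Ndn at −0.83 ± 0.08 and Ppp1r9a at 0.66 ± 0.06.

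Among inflammatory and matrix genes, Cxcl12 differed by −1.91 ± 0.09 and Icam1 by 1.37 ± 0.07 with AGi (6 of 20 lower, 3 higher). Of 30 hypoxia targets 6 were higher and 5 lower (3 lower without day 2 or day 4 and 2 without day 8), with Hk2 at 0.60 ± 0.08 and Ndrg1 at −0.90 ± 0.12. Of 25 genes of the TET and Jumonji list, 4 were higher (2 without day 10), such as Tet2 (0.39 ± 0.07), and 5 lower, such as Phf2 (−0.43 ± 0.07). Among all 13865 tested genes, 2722 were higher and 2675 lower (38.9% called). The counts of the hypoxia and the TET and Jumonji lists were near that share, so they show no response of these lists. Neither Tet2 nor Phf2 passed the test against the control difference. Ascorbic acid is a cofactor of TET and Jumonji enzymes. The list also holds the DNA methyltransferase genes Dnmt3a and Dnmt3b, so its counts are not of such enzymes alone. On days 2, 4 and 6 alone the counts were 3 lower and 2 higher for the inflammatory list, 1 and 1 for hypoxia targets, and 1 and 0 for TET and Jumonji genes.

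Over 475 X-linked genes the median was 0.42 higher in Fibroblast-iPSC than in ESCs and 0.23 higher in GMP-iPSC, against −0.03 and 0.0015 for other genes. Of 6503 unnamed probe sets, 661 were called with AGi, against 11 of 62 control probe sets. Among the 18 hybridisation controls alone, 11 were called.

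A hypothesis for the MEF-marking genes of Fibroblast-iPSC, whose induction was also longer than that of GMP-iPSC, is that fibroblast RNA, left from the donor culture or from feeder cells, was in that sample. With 1 common share of MEF RNA, 14.2%, added to GMP-iPSC, 88% of 25 fibroblast-list genes lay within 1 log2 of the level it gives (share quartiles 12.1% and 21.4%), including Col1a1, Postn and Mmp2; Lox and Fbln2 lay above it and Ogn below. The values go with the hypothesis of fibroblast RNA, but expression kept in the line may give the same, and 1 array cannot part them. The 25 genes were also chosen partly by a low level in GMP-iPSC, the array to which the share was added.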
